A study of Caenorhabditis elegans with 4 samples.

How the data were processed

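ChIP-seq was done on fed L1 hermaphrodites of strain YL409 grown at 20 °C, per the labels' protocols. Worms were fixed in 2% formaldehyde, chromatin was sonicated, and LIN-35::GFP was precipitated with affinity-purified antibodies against GFP. Input DNA was taken from the same supernatants. The 4 samples are 2 ChIP samples and 2 input samples, and each ChIP sample has its own peak list. The inputs enter no comparison of their own and were not analysed here.

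The authors deposited 3 peak lists, 1 per ChIP replicate and 1 named combined, in WormBase WS220 coordinates per the file headers. The source column of each list reads spp_via_IDR, which names the SPP peak caller and the irreproducible discovery rate, a measure of agreement between replicates. The aligner, the versions, the thresholds, the rule that made the combined list and the way input was used are not given in the sources used here. Each peak has a start, an end, a score and a peak number. The score values were deposited by the authors without a stated scale, so they were used to rank peaks within a list and, in a single alternative, as log2 values in a correlation across shared peaks. Scores had a ceiling, which 3446 peaks of replicate 1 reached (13.0%), 1401 of replicate 2 (4.88%) and 4370 of the combined list (91.2%). Peak numbers ran opposite to the scores in the replicate lists (Spearman's rho of -1.00 and -1.00) and less closely in the combined list (-0.49), where most scores tie. Peaks were therefore placed by score and, within ties, by peak number. Most peaks had a fixed width, 300 bp in replicate 1, 336 bp in replicate 2 and 324 bp in the combined list (98.1%, 95.9% and 71.8% of peaks). In the combined list 1 position occurs more than once, and both entries were kept.

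Everything else was computed from these lists with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6, and figures were drawn with matplotlib 3.10.9. Comparisons used the 6 nuclear chromosomes. Mitochondrial peaks were left out of them. The extent of a chromosome was taken as the largest peak end in any list, a lower bound on its length. Peaks counted as shared when they overlapped by at least 1 bp. The chance level came from 1000 circular shifts, in which all peaks of a chromosome move by 1 random distance and wrap around its end. Agreement of scores was measured by Spearman's rho over peaks with a single partner in either direction, with 100000 permutations. Peak density was counted by midpoint in whole windows of 1 Mb. X and autosomes were compared by permuting windows 100000 times, and 95% intervals of density ratios came from 10000 bootstrap draws of windows. The centre of a chromosome is the third of its extent around the middle and the arms are the rest, compared with 10000 circular shifts. Shares among the best 100, 500 and 1000 combined peaks were compared with the rest by Fisher's exact test, with Benjamini-Hochberg adjustment over 18 tests, and again among autosomal peaks alone over 15 tests. These treat peaks as independent. Wilson intervals and the limit set by a count of 0 cover counting error only.

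The comparisons, the peaks to be named (the 15 best of the combined list) and a set of alternatives were fixed before the data were examined. That plan compared X with autosomes, and centres with arms, as shares of genes with a peak. It also held tests of distance to transcription start sites, of 18 gene lists and families, of E2F-like and CHR-like motifs and of the transgene loci *lin-35*, *unc-119* and *dpl-1*. All of these need a WS220 annotation or genome. The gene table at hand uses WBcel235, and coordinates of different builds were not mixed, so these tests were not run and no peak was assigned to a gene. X and centres were compared by peaks per Mb instead. For X this measure was in the plan as a second choice, for centres it was not, and the tests by windows and by shifts replaced Fisher's exact tests of genes. Comparisons among all 6 chromosomes and the shares among the best 100, 500 and 1000 peaks were not in the plan. The density ratios among the best 500 peaks, X against single autosomes, the quotient of autosome and X ratios, the shares among autosomal peaks alone and the centre share of the best 500 were chosen after results had been seen.

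The procedures were tested on simulated lists of the real sizes. With 40% of replicate 1 peaks planted in replicate 2, the expected overlap of 49.8% with chance was found as 50.0%. A planted X to autosome ratio of 0.8 was found as 0.83, and a planted centre to arm ratio of 1.5 as 1.53. Among 100 lists with no difference, 6 fell under the threshold of 0.05 for X and 9 for centres in these permutation tests. The latter test may be somewhat liberal. Simulated peaks were placed independently of each other, whereas the real combined peaks were spaced unevenly. These rates may therefore not hold for the real lists.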

Results

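LIN-35 is the *Caenorhabditis elegans* member of the retinoblastoma protein family and a subunit of the DREAM complex, which binds promoters together with E2F and DP proteins and represses transcription. The series asked where in the genome LIN-35 is bound in fed larvae of the first larval stage (L1). The hermaphrodite larvae were of strain YL409, an *unc-119* mutant rescued by a transgene that expresses LIN-35 fused to GFP and FLAG from the *lin-35* promoter. Chromatin was crosslinked with formaldehyde and immunoprecipitated with an antibody against GFP, and input chromatin was kept from the same extracts. The 4 samples are 2 ChIP and 2 input samples. The labels number the replicates but do not say whether they came from separate cultures. The p-values below were computed over peaks, windows or shifted positions, and do not measure spread between replicates.

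The measurements are peak lists in WS220 coordinates. Replicate 1 held 26583 peaks and replicate 2 held 28727, whereas the combined list of the series held 4794. The combined peaks covered 1359 kb, or 1.36% of the nuclear genome spanned by the lists, against 7.81% for replicate 1 and 9.28% for replicate 2. The read depth behind the lists is unknown, because the lists give scores and not read counts. Peaks are referred to by their place, with place 1 the best-scoring peak of a list, and peaks tied in score placed by the authors' peak number.

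The strongest LIN-35::GFP sites lay on autosomes, and both replicates placed the same sites at the head of their lists. The best combined peak was on chromosome II at 10563347 to 10563660, and it had peak number 1 in replicate 1 and 2 in replicate 2. The next was on chromosome III at 3867377 to 3867708, with numbers 2 and 1. The third was on chromosome V at 10897200 to 10897533, with numbers 5 and 3, and the fourth on chromosome IV at 14464080 to 14464401, with numbers 3 and 4. Of the 15 best combined peaks, 7 were on chromosome III, 4 on II, 2 on IV, 1 on I and 1 on V, and 0 were on X. The other chromosome III sites started at 10758977, 7854461, 12904928, 11007618, 11719362 and 2151524. The remaining chromosome II sites started at 216632, 15010408 and 4999183, the other chromosome IV site at 17249713, and the chromosome I site at 12966753. These 15 peaks were 285 to 364 bp wide. Each overlapped 1 peak in either replicate, with peak numbers no lower in rank than 19 in replicate 1 and 27 in replicate 2. The genes and annotated features at these positions were not analysed here.

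The comparison of the replicates asked how far 2 immunoprecipitations found the same sites. Strong sites were found in both, and weak sites mostly in one. In the best 10% of each list, 99.6% of replicate 1 peaks and 98% of replicate 2 peaks overlapped a peak of the other replicate. In the last 10% this was 24.4% and 20.4%, against 17.2% and 16.3% after random circular shifts along the chromosomes. Of the best 1000 peaks by number in either replicate, 0 lacked a partner in the other. Over whole lists, 11105 of 26553 nuclear peaks of replicate 1 (41.8%, Wilson 95% interval 41.2 to 42.4%) overlapped replicate 2, and 11308 of 28703 of replicate 2 (39.4%, 38.8 to 40.0%) overlapped replicate 1. Shifted lists gave 17.3% and 16.2%, and the one-sided permutation p of 0.001 was the smallest that 1000 shifts can give for either direction. With both lists reduced to as many top peaks as the combined list holds, the shares were 70.1% and 70.3%, against 2.94% and 2.93% after shifts. Over the whole lists, with midpoints required to lie within 100 bp, they were 27.9% and 25.8%, against 5.82% and 5.37% after shifts.

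The positions of shared peaks lay closer together at combined peaks than elsewhere, and the scores of shared peaks were correlated. Among 9555 peaks with 1 partner in either direction, midpoints lay a median of 55 bp apart. The median was 23 bp among the 3973 of these pairs that overlap a combined peak, and 100 bp among the 5576 that overlap none. Required overlap itself limits these distances, and no chance distance was computed. Spearman's rho of the scores across all 9555 pairs was 0.66 (permutation p = 1e-05, the smallest possible). It was 0.30 in the pairs at combined peaks, where many scores sit at the ceiling. Peak numbers, which have no ceiling, gave rho = 0.72 over all pairs and 0.79 at combined peaks. These are correlations across peaks, which are not independent replicates. The combined list belongs to the same replicates, and its source column names a measure of agreement between replicates. Closer positions and the higher correlation of peak numbers at combined peaks may therefore be built in by the selection of those peaks.

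The combined list was also compared with the replicates it belongs to, so that this overlap is no independent check. Of the 4794 combined peaks, 4546 (94.8%) overlapped peaks of both replicates, 243 overlapped replicate 2 only, 4 overlapped replicate 1 only, and 1 overlapped neither. Shifted lists gave 6.01% in both (permutation p = 0.001). The combined list took up 92.5% of an equal number of top peaks of replicate 2, but 75.6% of those of replicate 1. A further 6390 peaks of replicate 1 overlapped replicate 2 and lay outside the combined list.

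**Figure D1:**
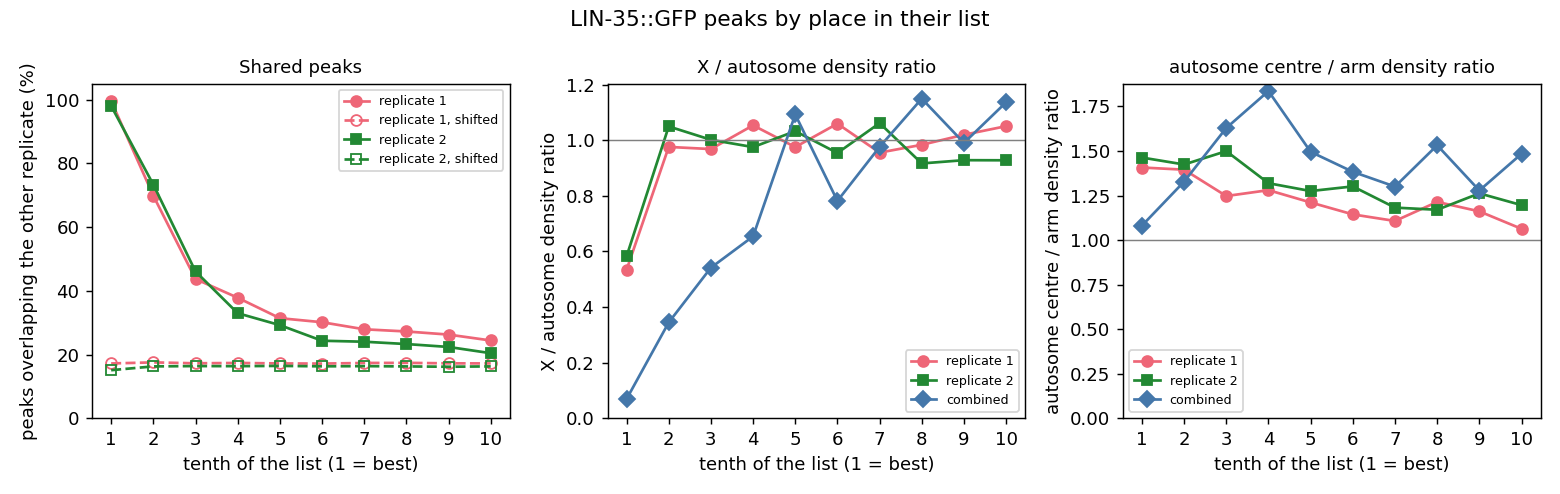
Peaks in 10 successive slices of equal size of their list (x axis, 1 is the best slice). Left, percentage of peaks that overlap the other replicate, with circularly shifted lists as dashed lines. Middle, peaks per Mb on X divided by peaks per Mb on autosomes. Right, peaks per Mb in the centres of autosomes divided by that on their arms. Points are values of single slices without error bars, and grey lines mark a ratio of 1. The combined list starts at an X to autosome ratio of 0.069 in its best slice of 480 peaks. Replicates 1 and 2 start at 0.53 and 0.58, in larger slices of 2656 and 2871 peaks. At an equal depth of the best 500 peaks, the ratios were 0.079 in the combined list, 0.089 in replicate 1 and 0.059 in replicate 2.

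Chromosomes differed in how densely they were bound. Chromosome III carried 66.9 ± 18.7 combined peaks per 1 Mb window (SD, n = 13 windows) and chromosome I 63.0 ± 16.4 (n = 15). Chromosome II carried 49.1 ± 16 (n = 15) and chromosome IV 45.9 ± 12 (n = 17). The lowest were X with 37.8 ± 7.27 (n = 17) and chromosome V with 32.8 ± 14.9 (n = 20). The 6 chromosomes differed in a permutation test over windows (p = 1e-05, the smallest possible). Among the 15 pairs, X was below I and III (Benjamini-Hochberg adjusted permutation p = 7e-05 for both), below II (0.022) and below IV (0.0342), whereas its difference from V was not resolved (0.25). The densest window was 8 to 9 Mb of chromosome III with 101 combined peaks, followed by 9 to 10 Mb of chromosome I with 93. The sparsest was 17 to 18 Mb of chromosome V with 7. In 1000 uniform placements with the same number per chromosome, the fullest window held a median of 82 peaks and at most 102, so that 101 was near the top of their range. These placements already hold the density of each chromosome, such as the high density of III. The emptiest held a median of 23 and at least 12, so that 7 was below their range.

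The X chromosome stood apart in its strong sites. Of the best 100 combined peaks 0 were on X, which allows a share of up to 3% by counting error, and of the best 500 there were 8 (1.6%), against 15.3% of the remaining combined peaks (odds ratio 0.0900, Fisher's exact test, two-sided, adjusted p = 8.94e-23 over 18 tests). The first X-linked peak, at 14101996 to 14102245, took place 216. Among the best 500, X carried 0.471 ± 0.717 peaks per Mb (SD, n = 17 windows) and the autosomes 5.94 ± 3.20 (n = 80), a ratio of 0.079 with a bootstrap 95% interval of 0.029 to 0.141. Both replicates showed this on their own. Their best 500 peaks gave ratios of 0.089 (interval 0.038 to 0.151) in replicate 1 and 0.059 (0.010 to 0.120) in replicate 2, with a permutation p of 1e-05 in each, the smallest possible. X was lower than each autosome taken alone among the best 500, including V, the sparsest autosome, at 3.8 ± 2.44 per Mb (n = 20). All 5 of these permutation p-values were 1e-05. Chromosome III held 125 of the best 500, but with X left out its share of autosomal peaks, 125 of 492 against 803 of 3637 of the rest, did not differ at the threshold (odds ratio 1.20, Fisher's exact test, adjusted p = 0.759 over 15 tests).

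In the whole combined list the deficit of X was smaller. X carried 37.8 ± 7.27 peaks per Mb (SD, n = 17 windows) and the autosomes together 49.9 ± 19.7 (n = 80), a ratio of 0.76 (bootstrap 95% interval 0.67 to 0.86, permutation p = 0.0155, two-sided). The X share was 1.46% (Wilson 95% interval 0.708 to 2.98%) in the best 10% of the combined list and 19.6% (16.3 to 23.4%) in the last 10%, whereas X made up 17.7% of the spanned genome. The difference over the whole list no longer passed the permutation test without chromosome I (ratio 0.81, bootstrap interval 0.71 to 0.93, p = 0.0635) or without chromosome III (0.81, 0.72 to 0.92, p = 0.0571). It passed without II (0.76, permutation p = 0.0192), without IV (0.74, p = 0.0152) and without V (0.68, p = 0.0002). Over all deposited peaks of replicate 1 or of replicate 2 it was not resolved either (ratios 0.96 and 0.95, permutation p = 0.483 and 0.436). Windows of one chromosome are not independent of each other. Permutation of windows also separated autosomes from each other, such as III from V (Benjamini-Hochberg adjusted permutation p = 7e-05). Chromosome V had a lower mean than X (32.8 against 37.8 per Mb), a difference that was not resolved. The whole-list difference is therefore not shown to be particular to X.

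**Figure D2:**
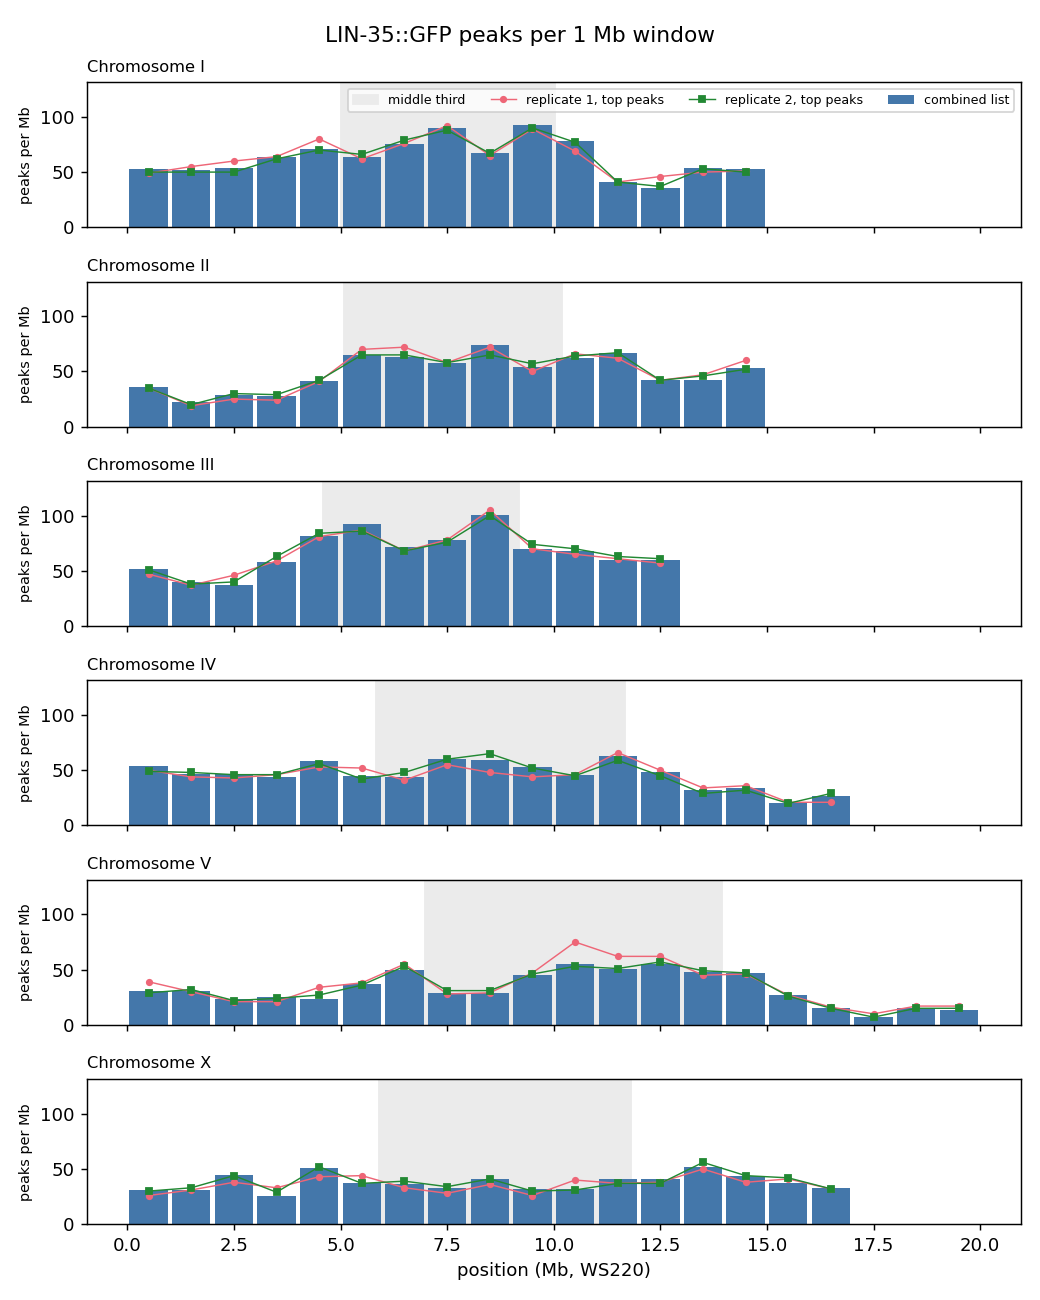
LIN-35::GFP peaks per 1 Mb window (y axis) along each chromosome (x axis, Mb, WS220). Bars show the combined list, circles and squares the same number of top peaks of replicate 1 and replicate 2, and grey shading the centre of the chromosome. The highest bar is 101 peaks on chromosome III and the lowest 7 on chromosome V, and the incomplete last window of each chromosome is left out.

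Autosomes were bound more densely in their centres than on their arms. In worms the autosome centres recombine rarely and hold more of the conserved and essential genes, and the arms hold more repeats. The centres of the 5 autosomes, the third of each around its middle, carried 1713 combined peaks, or 62.3 per Mb, and the arms 2416, or 43.9 per Mb. The ratio was 1.42 (bootstrap 95% interval 1.23 to 1.67, p = 0.0009 in a two-sided permutation test with circular shifts). The top peaks of replicate 1 and replicate 2, taken alone, gave 1.41 and 1.41 (permutation p = 0.001 in each). The ratio was above 1 on each autosome, from 1.27 on chromosome IV to 1.64 on V, although on single chromosomes the shifts did not resolve it (adjusted permutation p of 0.389 to 0.538). On X it was 0.96 (interval 0.79 to 1.08). With ratios of mean counts in whole 1 Mb windows instead, the autosome ratio divided by the X ratio was 1.56 (bootstrap 95% interval 1.26 to 1.91). Windows were assigned to centre or arms by their midpoints, so this value is not the quotient of the ratios given above. The same kind of bootstrap left out 1 on each single autosome, such as IV (1.08 to 1.60), where the shifts did not resolve the ratio. Its intervals may thus be too narrow, and no test with shifts compared autosomes with X.

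The central excess had a lower value among the best 500 peaks, but no test that allows for the uneven spacing of peaks compared it with the whole list. Among the best 500 combined peaks the autosome centres carried 6.25 and the arms 5.82 per Mb, a ratio of 1.08 with an interval of 0.83 to 1.35 (permutation p = 0.589). Of these best peaks on autosomes 35% lay in the centres, against 42.4% of the remaining autosomal combined peaks (odds ratio 0.73, Fisher's exact test, p = 0.00179). The best 500 of replicate 1 gave a ratio of 1.08 (permutation p = 0.575) and those of replicate 2 a ratio of 1.13 (permutation p = 0.374). Their centre shares were 35% against 42.3% of the other top peaks (Fisher's exact test, p = 0.00246) and 36% against 42.1% (p = 0.0113). These Fisher tests were not adjusted, were chosen after results had been seen and treat peaks as independent. The combined list belongs to the same replicates, so the shares of the single replicates are not separate support. The interval of 0.83 to 1.35 overlaps that of the whole list, 1.23 to 1.67. The lower ratio did not reach far down the lists. The better-placed part of the combined list (2397 peaks, all tied at the ceiling score) gave 1.44, and the best 10% of each replicate 1.41 and 1.46.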

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

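Both replicate lists held peaks on the mitochondrial genome, which no comparison used. Replicate 1 had 30 and replicate 2 had 24, whereas the combined list had 0. They stood high in their lists: the best had peak number 187 in replicate 1 and 415 in replicate 2, and their median score in replicate 1 was the ceiling of the list, 3.84. Their density was 2.17 and 1.73 peaks per kb, against 0.265 and 0.286 per kb on the nuclear chromosomes. They made up 0.113% and 0.0836% of their lists. The count of 0 in the shorter combined list allows a share of up to 0.0626% by counting error.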

How the results depend on the processing

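Of 48 alternative values, 41 kept their direction and their side of the threshold of 0.05 in permutation tests, 7 kept their direction but no longer passed, and 0 reversed. For X, 4 of 19 no longer passed, and for centres 3 of 14. The total is no measure of robustness, since all overlap and correlation alternatives sat at the smallest possible permutation p. The X alternatives among the best 500 measured a larger deficit than the whole-list ratio and were chosen after that deficit had been seen. The better part of the combined list by peak number held the same 2397 peaks as that by score and was not counted again. The X to autosome ratio of 0.76 no longer passed over all peaks of replicate 1 (0.96) or of replicate 2 (0.95), nor without chromosome I (0.81) or chromosome III (0.81). Its permutation p ranged from 1e-05 to 0.483. Chromosomes I and III are the densest; the cause of the other changes was not tested. The centre to arm ratio of 1.42 no longer passed among the best 500 peaks of the combined list (1.08), of replicate 1 (1.08) or of replicate 2 (1.13), and the cause was not tested; its p ranged from 0.0001 to 0.589. The top 4794 peaks of replicate 1 alone and of replicate 2 alone gave X ratios of 0.72 and 0.77. Replicate overlap ranged from 27.9% to 70.1% for replicate 1 and from 25.8% to 70.3% for replicate 2, agreement of scores from 0.30 to 0.61, and that of peak numbers was 0.72, or 0.79 at combined peaks. The share of combined peaks found in both replicates ranged from 80.3% to 99.2%. The alternatives by single autosome, by windows of 500 kb, by peak number alone, over all replicate peaks and over the best 500 peaks, and the correlation of peak numbers, were chosen after seeing the data, those of the best 500 after seeing results. No paired analysis was possible because the input samples that share replicate numbers with the ChIP samples enter with no peak list or values here. Alternatives on start sites, gene shares, gene lists, motifs and peak summits were not run, since no WS220 annotation, genome or summit was used here. Depth is unknown, so the weak peaks of either replicate cannot be weighed by reads.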

Other observations

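The tests on X, the tests of read coverage on whole lists and the stretch on chromosome V were chosen after results had been seen, and the tests on centres by the combining step and by peaks outside the combined list were written before. Combined peaks were spaced unevenly. The median distance between neighbouring midpoints was 10832 bp, below the range of 13034 to 14655 bp over 1000 random placements with the same number per chromosome. Of 4788 distances, 6.98% were 1 kb or less (4.05 to 6.10% at random) and 2.32% were 100 kb or more (0.814 to 1.55%). The longest stretch without a combined peak was on the right arm of chromosome V, from 16965816 to 17538671, a distance of 573 kb that exceeded the longest of any random placement, 506819 bp. Replicate 1 had 91 peaks and replicate 2 had 44 in this stretch that overlap no combined peak, or 159 and 76.8 per Mb, against 207 and 213 per Mb of such peaks over the whole chromosome.

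The X chromosome carried few strong LIN-35::GFP sites in the combined list. A loss of X peaks in the combining step is argued against by the single replicates. Their top 4794 peaks gave X to autosome ratios of 0.72 (0.64 to 0.81) and 0.77 (0.68 to 0.87). For strong sites, their best 500 peaks gave 0.089 (0.038 to 0.151) and 0.059 (0.010 to 0.120). Lower read coverage of the X stays open: all peaks of replicate 1 and of replicate 2 gave 0.96 (0.89 to 1.04) and 0.95 (0.87 to 1.03), but how the number of weak peaks follows coverage is unknown. Replicate peaks outside the combined list gave 1.01 (0.94 to 1.09) and 0.98 (0.90 to 1.07), above the 0.76 of the combined list, but cannot decide it, since lower coverage would itself move X peaks out of that list. Whether the X has fewer LIN-35 target promoters or less binding at each stays open too, and no biological explanation was tested.

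The excess of combined peaks in autosome centres was weighed against the combining step and uneven read coverage. The top peaks of the single replicates gave centre to arm ratios of 1.41 (1.22 to 1.66) and 1.41 (1.24 to 1.66), which argues against the combining step. Uneven coverage stays open and may account for some or all of the excess: all peaks of replicate 1 and of replicate 2 were also denser in the centres, by 1.22 (1.15 to 1.32) and 1.31 (1.19 to 1.45). The test written before used replicate peaks outside the combined list, whose ratios of 1.18 (1.12 to 1.252) and 1.28 (1.18 to 1.41) left out the 1.42 of the combined list and so met its bound against coverage, but it was set aside afterwards, since higher coverage would itself lift centre peaks into that list. Gene density was not tested and stays open, as does any biological difference.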
